A study of Homo sapiens with 24 samples.

How the data were processed

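RNA was measured in 24 libraries of HEK293T cells, 3 for each of 2 lines in 4 treatments. The files hold 1 table per library with estimated counts per transcript, effective lengths and transcript lengths, which the authors deposited. Per the submitters' notes reads were 38 bases from each end (Nextera XT libraries from SmartSeq2-type cDNA, Illumina NextSeq), checked with FastQC and quantified with kallisto 0.46.1 against GRCh38. The release of the transcript index is not stated. Of 190522 transcripts in each file, 169111 matched GENCODE v29 by identifier without version and 21411 did not. Unmatched transcripts held 2.55 to 2.9% of counts per library and were left out. Estimated counts were summed per gene over 35568 genes and rounded. Mitochondrial 16S-like MTRNR2L genes held 18.7 to 27.1% of counts and the pseudogene ENSG00000225840 2.97 to 7.81%; both stayed in the library totals of the main test. Between 10439 and 12069 genes per library had at least 10 counts, and mitochondrial mRNAs made up 3.22 to 6.08% of gene counts. No pair of replicates was a duplicate (chi-square per degree of freedom 2.63 to 11.87).

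The main test was the edgeR quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with robust dispersion, TMM scaling and filterByExpr, in 1 fit of 8 group means over 24 libraries with no batch term. P-values were adjusted by Benjamini-Hochberg within each of 11 contrasts, and a gene is called at an adjusted p below 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Contrasts, gene lists, alternatives and the rule for named genes were set before the data were examined. Later additions were the length and GC offsets, the block within each line, the settings without the mitochondrial 16S-like genes and without 5 WT libraries, and the comparisons of CG8 with WT under treatment. DESeq2 1.42.0 and limma 3.58.1 gave the other tests, and tables and plots were made with Python 3.11.15.

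Gene lists (39, of which 34 had at least 5 tested genes) were tested with limma camera on voom values at a preset correlation of 0.01, adjusted over the 34 lists of a contrast. Beside it stand camera with a correlation estimated from the residuals and fry. Lists with fewer tested genes were not tested. Members are also counted after adjustment over the list alone.

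Genes are named by a fixed rule: the 8 largest rises and falls past the test with a mean of at least 5 CPM in the higher group and no overlap between the groups (4 each for interactions, without that last condition); up to 4 members of each called list; 10 genes chosen beforehand for harman, fibril and stress effects; and, where no gene was called, the 3 lowest p-values. Pseudogenes and families of near-identical genes were passed over. With 3 libraries against 3, 10% of random orderings show no overlap. Coordinates are GRCh38 from GENCODE v29.

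Labels name batches A, B and C, so letters may pair the libraries. Residuals of libraries with the same letter in the same line correlated with a median r of 0.29 (-0.08 to 0.565, 32 of 36 pairs above 0.1), against 0.04 for the same letter across lines (4 of 48 pairs above 0.1). Letters thus pair libraries within a line, and hardly across lines. The replicate block, which fits a letter effect shared by both lines, was kept as an alternative, as planned, and its counts are printed beside the main ones. The block within each line, added later, follows this pairing more closely.

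In a self-test 200 genes were changed in silico in counts without any other effect. Of changes of 1.5-, 2- and 3-fold the fit recovered 6%, 68.7% and 90.9% in a design like PFF in CG8 (116 called, 6 of them false), 10.4%, 74.6% and 89.4% in one like harman in CG8 (120 called, 4 false) and 0%, 25.4% and 63.6% for the interaction (62 called, 3 false).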

Results

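HEK293T cells (WT) and a HEK293T line that carries a reporter with GFP and mCherry (CG8) were compared by RNA sequencing in 4 treatments. These were untreated, sonicated pre-formed fibrils at 4 µg/mL (PFF), harman at 80 µM, and PFF with harman. Harman is a β-carboline that the series describes as an inhibitor of aggregation. Each of the 8 groups holds 3 libraries, from batches A, B and C, so 24 libraries enter the main fit. Totals ran from 2246850 to 4404838 estimated counts per library (median 2786400), and 12771 genes were tested. Lipofectamine and 0.8% DMSO were present in all groups. Values below are log2 fold changes ± standard error from edgeR, CPM as mean ± SD, and p adjusted over all tested genes. P-values measure the spread between these samples, and whether the replicates were separate cultures is not stated.

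Several genes had no counts in untreated WT: ASTN1, a neuronal adhesion protein (chromosome 1 at 176857302–177164973, GRCh38), was at least 30-fold higher in untreated CG8, XKR5 at least 17.4-fold and the potassium channel KCNA1 at least 12.4-fold. CLCN4, a chloride-proton exchanger (4.91 ± 0.68), ARHGAP20 (4.46 ± 0.83) and the kinase PRKCB (4.36 ± 0.76) rose with them. CA2, carbonic anhydrase 2, fell by 2.18 ± 0.21 (23.5 ± 5.75 CPM (SD, n = 3) against 107 ± 13.1). ARL6, a GTPase of the cilium (-2.27 ± 0.29), the splicing regulator ESRP2 (-2.02 ± 0.38), the chemokine receptor CXCR4 (-1.95 ± 0.46) and ODC1, which makes polyamines (-1.87 ± 0.34), fell as well. MAOA, an amine oxidase that β-carbolines inhibit, rose by 1.87 ± 0.50 (5.75 ± 2.39 CPM (SD, n = 3) against 1.5 ± 0.623, adjusted p = 0.0193). Floors for genes at 0 assume 3 counts over the group and cover counting error only, since the libraries carry no molecular barcodes.

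Amino-acid stress genes were low in untreated CG8. Of 33 targets of ATF4, the transcription factor of the integrated stress response, 17 fell and 1 rose (21 and 1 adjusted over the list alone). Their median was -0.75 (limma camera adjusted p = 1.2e-14, adjusted p = 0.0439 with an estimated correlation). SLC7A5, an amino-acid transporter, fell by 1.33 ± 0.17 (adjusted p = 4.99e-05). ASNS, asparagine synthetase (-1.19 ± 0.16, 81.1 ± 7.51 CPM (SD, n = 3) against 185 ± 34.6), and ATF4 itself (-1.0 ± 0.14) fell too. Of 28 ribosome biogenesis genes 15 fell (21 adjusted over the list alone), among them RCL1 (-1.54 ± 0.21) and GNL3 (-1.27 ± 0.20), both of the nucleolus. That list's median was -0.71 (adjusted p = 1.97e-15, adjusted p = 0.0439 with an estimated correlation). These are the only lists of this comparison that hold with an estimated correlation, and with the replicate block added the ATF4 list does not (adjusted p = 0.0608 with an estimated correlation).

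Cytosolic ribosomal protein genes were lower in CG8 as well, where 29 of 57 fell (44 adjusted over the list alone), RPL14 by 1.21 ± 0.18 and RPS7 by 1.26 ± 0.20. Their median was -0.64 (adjusted p = 2.51e-22, adjusted p = 0.219 with an estimated correlation), and -0.38 with length and GC offsets. They made up 3.35 ± 0.356% of gene counts (SD, n = 3) in untreated CG8 and 4.75 ± 1.11% in untreated WT, while genes with transcripts above 4 kb made up 23.5% and 20.8%. Replication-dependent histones fell in 9 of 26 cases (10 adjusted over the list alone), the linker histone H1-4 from 1810 ± 197 to 792 ± 178 CPM (SD, n = 3). The histone median was -0.74 (adjusted p = 5.06e-08, adjusted p = 0.229 with an estimated correlation). Glycolysis genes fell in 4 of 28 cases (7 and 1 rise adjusted over the list alone), enolase ENO1 by 1.26 ± 0.20, with a median of -0.44 (adjusted p = 0.00162, adjusted p = 0.318 with an estimated correlation). Splicing factors fell in 6 of 24 (12 adjusted over the list alone, median -0.34, adjusted p = 1.69e-05, adjusted p = 0.0582 with an estimated correlation).

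Proteasome subunits fell in 4 of 32 cases (8 and 1 rise adjusted over the list alone, median -0.34 and -0.15 with offsets, adjusted p = 0.000182, adjusted p = 0.447 with an estimated correlation). Nuclear genes of the respiratory chain fell in 9 of 43 (9 adjusted over the list alone, median -0.30, adjusted p = 1.69e-05, adjusted p = 0.36 with an estimated correlation), a call lost with length and GC offsets (adjusted p = 0.201). Of 30 S phase genes 2 rose and 2 fell (3 and 2 adjusted over the list alone, median -0.25, adjusted p = 0.0281, adjusted p = 0.177 with an estimated correlation). Cholesterol synthesis genes fell in 3 of 26 cases (3 and 1 rise adjusted over the list alone), DHCR7 by 0.90 ± 0.15, with a median of -0.27 and -0.18 with offsets (adjusted p = 0.0228, adjusted p = 0.132 with an estimated correlation). Targets of the unfolded protein response (ATF6 and XBP1) fell in 4 of 25 (5 adjusted over the list alone, median -0.23, adjusted p = 0.0163, adjusted p = 0.0881 with an estimated correlation), but HSPA5, a chaperone of the endoplasmic reticulum, did not pass (-0.23 ± 0.15, adjusted p = 0.362). HSF1 targets fell in 7 of 19 and rose in 1 (7 and 2 adjusted over the list alone, median -0.30, adjusted p = 0.0281, adjusted p = 0.342 with an estimated correlation). NRF2 targets fell in 5 of 21 (7 adjusted over the list alone), PRDX1 by 0.94 ± 0.20, with a median of -0.24 (adjusted p = 0.0281, adjusted p = 0.0881 with an estimated correlation, and adjusted p = 0.219 with offsets).

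Interferon-stimulated genes stood higher in CG8: OAS3, a sensor of double-stranded RNA, rose by 2.30 ± 0.51 (21.3 ± 5.56 CPM (SD, n = 3) against 4.4 ± 3.33, adjusted p = 0.00603). It was the only call among 17, also adjusted over the list alone (median 0.66, adjusted p = 0.0233, adjusted p = 0.167 with an estimated correlation). TGF-β targets gave 2 rises in 11 (3 and 1 fall adjusted over the list alone), fibronectin FN1 (0.83 ± 0.14) and the pathway's feedback regulator SKIL (0.88 ± 0.25). Their median was 0.83 (adjusted p = 0.0315, adjusted p = 0.114 with an estimated correlation). In all, edgeR called 1182 genes between the untreated lines, 452 higher and 730 lower in CG8, and 1904 with the batch letter as a replicate block. Length-scaled TPM counts gave 528, the compared groups fitted alone 680 and a test against 1.2-fold 489. Leaving out CG8 untreated B gave 569, CG8 untreated C 664 and WT untreated A 578. The lines may differ in more than the reporter, so no gene here can be assigned to it as such. The WT libraries of batch A and the WT library of PFF with harman from batch B lie apart from the rest on PC1 (29.9 to 46.2 against at most 19.5, 36.2% of variance).

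Fibrils alone moved 12 genes in CG8 without a batch term, and 669 with a block within each line. CLTC, the clathrin heavy chain of endocytic coats (chromosome 17 at 59619689–59696956), rose by 0.76 ± 0.12 (399 ± 20.9 CPM (SD, n = 3) against 235 ± 14.4, adjusted p = 0.0158). So did the mRNA decapping enzyme DCP2 (0.81 ± 0.16, adjusted p = 0.0368, but -0.02 with length-scaled TPM counts) and ZNF275 (0.75 ± 0.15, adjusted p = 0.0473). FAU, a ribosomal protein fused to a ubiquitin-like domain, fell by 1.19 ± 0.22 (31.9 ± 2.58 CPM (SD, n = 3) against 73.1 ± 13.2, adjusted p = 0.0349). MRPL28 of the mitochondrial ribosome (-1.08 ± 0.19), the splicing protein SNRPC (-1.06 ± 0.21), the actin-binding TMSB10 (-1.03 ± 0.19) and RPLP1 of the ribosomal stalk (-0.99 ± 0.19) fell too. The ornithine decarboxylase antizyme OAZ1 (-0.80 ± 0.16), the helicase DDX27 (-0.72 ± 0.13) and nucleolin NCL (-0.65 ± 0.13) complete the falls. HSPA5, HMOX1, SQSTM1 and DDIT3, markers of chaperone load, oxidative stress, autophagy and lasting stress, did not pass (-0.28, 0.10, 0.24 and -0.43).

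Ribosomal protein genes were lower under fibrils in CG8, where 1 of 57 fell (42 adjusted over the list alone). Their median was -0.59, or -0.29 with length and GC offsets (adjusted p = 1.44e-28, adjusted p = 0.617 with an estimated correlation), and their share of gene counts went from 3.35 ± 0.356% to 2.39 ± 0.0115% (SD, n = 3). The share of genes above 4 kb went from 23.5% to 25.6%. Proteasome subunits had 0 of 32 past the test (9 falls adjusted over the list alone) and a median of -0.36, or -0.22 with offsets (adjusted p = 1.13e-07, adjusted p = 0.617 with an estimated correlation). Respiratory chain genes had 0 of 43 (6 falls adjusted over the list alone) and a median of -0.30 (adjusted p = 8.12e-09, adjusted p = 0.617 with an estimated correlation, and adjusted p = 0.0616 with offsets). Endocytosis genes, with CLTC the only call in 24, gave a median of 0.14 (adjusted p = 0.183). Autophagy, lysosome, HSF1 and Parkinson disease genes stayed near 0 (medians -0.01, -0.02, -0.04 and 0.05, adjusted p = 0.65, 0.868, 0.78 and 0.966).

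The whole fibril count in CG8 was 12 genes, 4 higher and 8 lower. It was 258 with the replicate block (64 higher), 153 by DESeq2 and 16 with length and GC offsets (9 higher). No gene passed with length-scaled TPM counts or in a test against 1.2-fold, while 78 did with the compared groups alone, 205 without the filter on low counts and 31 with a stricter one. With offsets ZNF275, SNRPC, TMSB10, RPLP1 and OAZ1 no longer passed (adjusted p = 0.0556, 0.0764, 0.179, 0.0509 and 0.133). No gene passed without CG8 untreated A or B, and 3, 4 and 1 did without the PFF libraries A, B and C. All 12 called genes, which include the pseudogene GNL3LP1 (5.85 ± 1.17), had the same sign in WT. Across these genes, which are not independent replicates, r was 0.73 with slope 0.16, and over all 12771 genes r was 0.23. The 12 genes were chosen by passing in CG8, which can raise r and lower the slope. GNL3LP1 has by far the largest fibril effect of the 12, so that r of 0.73 and its slope lean on this pseudogene.

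WT cells gave no call for fibrils (edgeR 0 genes, 931 at unadjusted p below 0.05, DESeq2 0), but 33 passed without the filter on low counts and 96 with a block within each line. The lowest p-values belonged to SENP3, a SUMO protease (1.47 ± 0.33), ZNF397 (-0.66 ± 0.15) and the ribosome recycling factor ABCE1 (0.69 ± 0.17, 510 ± 65.1 CPM (SD, n = 3) against 315 ± 43.9), each at adjusted p = 0.617. Of 4 lists that moved, none has a member past the test, over all genes or adjusted over the list alone. Ribosomal protein genes had a median of -0.38, or -0.21 with length and GC offsets (camera adjusted p = 7.08e-20, adjusted p = 0.873 with an estimated correlation). Proteasome subunits had -0.31 (adjusted p = 3.14e-07, adjusted p = 0.873 with an estimated correlation). Respiratory chain genes had -0.21 (adjusted p = 1.22e-06, adjusted p = 0.873 with an estimated correlation, and adjusted p = 0.0636 with offsets). All 15 immediate early genes, which answer growth signals within minutes, stood higher (median 0.48, adjusted p = 0.0102, adjusted p = 0.873 with an estimated correlation, but adjusted p = 0.0323 with the block and an estimated correlation), DUSP1 by 1.16 ± 0.66 and FOS by 0.56 ± 0.37.

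When the fibril effects of both lines were compared directly, no gene was called (edgeR 0, 336 at unadjusted p below 0.05, DESeq2 0). In the self-test the interaction of harman and fibrils recovered 25.4% of 2-fold changes, so differences of that size can be missed. Without CG8 PFF library B 1 gene passed, and without the filter on low counts 16 did. SLC15A1, a peptide transporter (3.50 ± 0.89), and the splicing factor CWC22 (-0.86 ± 0.22) came nearest, both at adjusted p = 1. Only the ribosomal protein list differed, by a median of -0.22 with 0 of 57 genes past the test, also adjusted over the list alone (adjusted p = 0.000757, adjusted p = 0.984 with an estimated correlation). This was lost with length and GC offsets (median -0.09, adjusted p = 0.463).

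**Figure D1:**
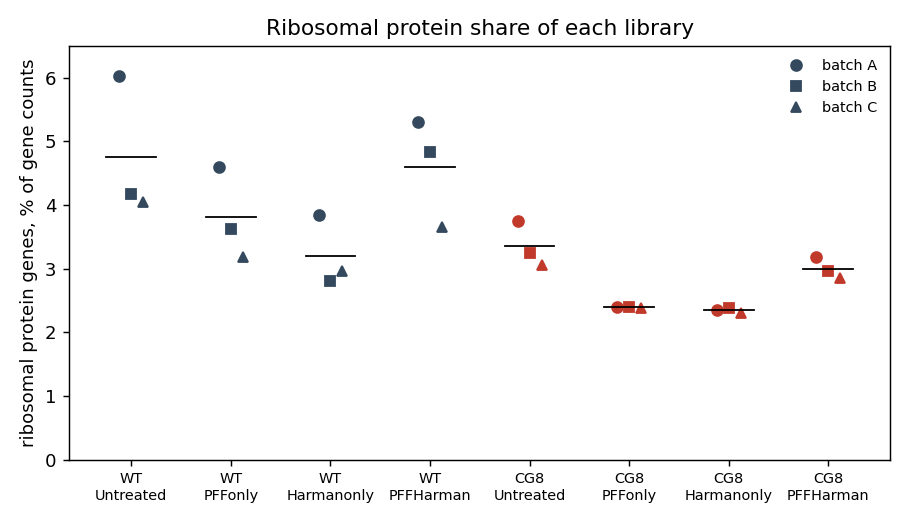
Share of each library's gene counts that falls on cytosolic ribosomal protein genes, by line and treatment, with batch letters.

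Harman raised p53 targets in CG8. EDA2R, a death receptor of the TNF family (chromosome X at 66595637–66639298), rose by 2.28 ± 0.33 (52.5 ± 23.3 CPM (SD, n = 3) against 10.7 ± 1.17, adjusted p = 0.000453). The ribonucleotide reductase subunit RRM2B rose by 1.63 ± 0.26 (adjusted p = 0.00102), SESN1, a brake on mTORC1, by 1.49 ± 0.32, the death receptor TNFRSF10B by 1.21 ± 0.25 and the DNA damage sensor DDB2 by 1.05 ± 0.23. Of 21 p53 targets 7 rose (11 adjusted over the list alone, median 0.58, adjusted p = 5.76e-10, adjusted p = 0.0115 with an estimated correlation). EDA2R is not on that list. Other large rises were MGAM, a brush-border glucosidase (3.45 ± 0.70), INPP5D (1.82 ± 0.49), SLFN5 (1.78 ± 0.31) and the cholesterol exporter ABCA1 (1.75 ± 0.40). The transcription factor MYC fell by 1.84 ± 0.33 (7.49 ± 3.39 CPM (SD, n = 3) against 27.4 ± 9.66). ODAD2, a dynein-docking protein of cilia (-3.33 ± 0.80), the ligand WNT10B (-2.67 ± 0.55), ABTB3 (-2.09 ± 0.55), the histone H2BC13 (-1.89 ± 0.50) and CAMKV (-1.89 ± 0.34) fell too. MAOA (-0.18 ± 0.42), DYRK1A, a kinase that β-carbolines such as harmine inhibit (0.46 ± 0.18), and CYP1B1, a target of the aryl hydrocarbon receptor (1.26 ± 0.55), did not pass (adjusted p = 0.897, 0.185 and 0.236).

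NRF2 targets, the antioxidant set, fell under harman in CG8 in 4 of 21 cases (7 adjusted over the list alone), PRDX1 by 0.78 ± 0.20. Their median was -0.47 (adjusted p = 1.18e-05, adjusted p = 0.00339 with an estimated correlation). Cholesterol synthesis genes fell in 3 of 26 (5 adjusted over the list alone), including DHCR7 (-0.80 ± 0.15) and squalene epoxidase SQLE (-0.81 ± 0.16). Their median was -0.27 (adjusted p = 0.000774, adjusted p = 0.0478 with an estimated correlation). Among ATF4 targets 4 of 33 fell and 1 rose (12 and 1 adjusted over the list alone), with SLC7A5 at -1.36 ± 0.18 and ASNS at -0.92 ± 0.16. The ATF4 median was -0.26 (adjusted p = 3.5e-05, adjusted p = 0.297 with an estimated correlation). HSPA5 fell by 0.69 ± 0.15 (adjusted p = 0.0107). HSPA8, the constitutive cytosolic chaperone, fell by 0.86 ± 0.21 as the only call of 19 HSF1 targets (5 falls and 2 rises adjusted over the list alone, median -0.29 and -0.19 with offsets, adjusted p = 0.0132, adjusted p = 0.31 with an estimated correlation).

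Ribosome biogenesis genes fell in 5 of 28 cases under harman (10 adjusted over the list alone, median -0.44, adjusted p = 5.76e-10, adjusted p = 0.0913 with an estimated correlation, but adjusted p = 0.0178 with the block and an estimated correlation). MYC, MYBBP1A (-0.84 ± 0.15) and GNL3 (-0.97 ± 0.21) were among them. Ribosomal protein genes fell in 8 of 57 (41 adjusted over the list alone), RPL8 by 0.65 ± 0.14, with a median of -0.58, or -0.25 with offsets (adjusted p = 1.66e-22, adjusted p = 0.297 with an estimated correlation). Their share of counts was 2.35 ± 0.0351% (SD, n = 3), and that of genes above 4 kb 27.1% against 23.5%. Histone genes fell in 8 of 26 (10 adjusted over the list alone, median -0.61 and -0.23 with offsets, adjusted p = 5.63e-07, adjusted p = 0.31 with an estimated correlation), H1-4 by 1.35 ± 0.18. Glycolysis genes fell in 2 of 28 (11 adjusted over the list alone, median -0.46, adjusted p = 2.25e-06, adjusted p = 0.238 with an estimated correlation), GPI by 0.56 ± 0.14 and ENO1 by 0.78 ± 0.20. Proteasome subunits fell in 2 of 32 (8 adjusted over the list alone, median -0.38 and -0.20 with offsets, adjusted p = 2.6e-07, adjusted p = 0.311 with an estimated correlation). Respiratory chain genes had 0 of 43 past the test (8 falls adjusted over the list alone, median -0.34, adjusted p = 1.06e-06, adjusted p = 0.311 with an estimated correlation, and adjusted p = 0.235 with offsets).

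In CG8 harman changed 387 genes, 172 up and 215 down. The replicate block gave 865, DESeq2 611, length and GC offsets 182, and length-scaled TPM counts 56, of which 17 were up. A test against 1.2-fold gave 93 and a block within each line 1550. Without harman A, B or C the count was 246, 158 or 143, and without untreated A, B or C it was 156, 196 or 236.

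P53 targets rose under harman in WT cells as well. EDA2R rose by 2.73 ± 0.42 (21.3 ± 8.46 CPM (SD, n = 3) against 3.17 ± 0.594, adjusted p = 0.000648). The cell-cycle inhibitor CDKN1A (chromosome 6 at 36676460–36687339) rose by 1.99 ± 0.44 (178 ± 19.3 CPM (SD, n = 3) against 44.5 ± 3.18). ZMAT3, a p53-induced RNA-binding protein (1.69 ± 0.36), the cation-chloride cotransporter SLC12A4 (1.62 ± 0.35), SESN1 (1.57 ± 0.37), the repressor SPEN (1.56 ± 0.27) and smooth-muscle actin ACTA2 (1.43 ± 0.32) rose too. Of the genes named as rising here, only CDKN1A, ZMAT3 and SESN1 are on the tested p53 list. The cystine transporter SLC7A11 fell by 1.88 ± 0.28 (55.7 ± 13 CPM (SD, n = 3) against 206 ± 11.4). LSM14A of processing bodies (-2.64 ± 0.60), H1-4 (-1.50 ± 0.18) and CHAC1, which degrades glutathione (-1.49 ± 0.40), also fell. HSPA5 (-0.80 ± 0.15, adjusted p = 0.0041) and haem oxygenase HMOX1 (-0.97 ± 0.26, adjusted p = 0.0345) fell, while MAOA (0.62 ± 0.54), DYRK1A (0.22 ± 0.19) and CYP1B1 (1.56 ± 0.59, adjusted p = 0.154) did not pass.

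ATF4 targets fell under harman in WT in 14 of 33 cases (19 adjusted over the list alone), with ASNS at -1.28 ± 0.16, SLC7A5 at -1.31 ± 0.17 and ATF4 at -0.94 ± 0.14. Their median was -0.60 (adjusted p = 6.67e-17, adjusted p = 0.0194 with an estimated correlation). Targets of the unfolded protein response fell in 2 of 25 (5 adjusted over the list alone), HSPA5 and HERPUD1 (-0.88 ± 0.17), with a median of -0.34, or -0.20 with length and GC offsets (adjusted p = 0.000625, adjusted p = 0.0194 with an estimated correlation). NRF2 targets fell in 4 of 21 (7 adjusted over the list alone, median -0.39 and -0.20 with offsets, adjusted p = 3.77e-05, adjusted p = 0.00615 with an estimated correlation). P53 targets rose in 7 of 21 (10 and 1 fall adjusted over the list alone, median 0.67, adjusted p = 1.13e-07, adjusted p = 0.0194 with an estimated correlation). Ribosome biogenesis genes fell in 3 of 28 (12 adjusted over the list alone, median -0.46, adjusted p = 1.75e-11, adjusted p = 0.0468 with an estimated correlation), all of them NCL (-0.78 ± 0.13), GNL3 (-0.82 ± 0.19) and MYC (-1.13 ± 0.27).

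Ribosomal protein genes fell in 16 of 57 cases in WT (47 adjusted over the list alone, median -0.64 and -0.33 with offsets, adjusted p = 1.26e-30, adjusted p = 0.159 with an estimated correlation, but adjusted p = 0.0342 with the block and an estimated correlation), RPL12 by 1.08 ± 0.20. Histones fell in 6 of 26 (6 adjusted over the list alone, median -0.33, adjusted p = 8.1e-06, adjusted p = 0.366 with an estimated correlation), a list call that offsets removed (median -0.04, adjusted p = 0.187). The splicing factor HNRNPA1 (-0.80 ± 0.15) was the only call of 24 in its list (8 falls and 1 rise adjusted over the list alone, median -0.15, adjusted p = 0.00931, adjusted p = 0.215 with an estimated correlation). CYP51A1 (-0.63 ± 0.14) was the only call of 26 cholesterol synthesis genes, also adjusted over the list alone (median -0.12, adjusted p = 0.0251, adjusted p = 0.159 with an estimated correlation). Glycolysis genes fell in 2 of 28, GPI and ENO1 (8 adjusted over the list alone, median -0.39, adjusted p = 1.52e-06, adjusted p = 0.159 with an estimated correlation). Among proteasome subunits 1 of 32 fell, PSMC4 (1 adjusted over the list alone, median -0.34 and -0.17 with offsets, adjusted p = 6.22e-06, adjusted p = 0.387 with an estimated correlation). Among respiratory chain genes 1 of 43 fell, COX5A (1 adjusted over the list alone, median -0.28, adjusted p = 1.67e-06, adjusted p = 0.366 with an estimated correlation, and adjusted p = 0.404 with offsets).

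The harman count in WT was 361, 178 up and 183 down. The replicate block gave 850, DESeq2 626 and offsets 216. With the mitochondrial 16S-like genes left out it was 401, of which 145 were up, and with length-scaled TPM counts 104, of which 36 were up. The compared groups alone gave 66, a stricter filter 547, a test against 1.2-fold 82 and a block within each line 1577. Without harman B it was 77, without harman C 175, and without untreated A, B or C 186, 204 or 213.

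Both lines shared the harman response: 79 genes rose and 92 fell in both (2.4 and 3.1 expected if independent), and 0 went opposite ways. Of the 387 CG8 calls, 383 had the same sign in WT. Across these genes, which are not independent replicates, r was 0.85 with slope 0.59, and over all genes r was 0.40. The 387 genes were chosen by passing in CG8, which can raise r and the CG8 effects. The slope therefore does not show a weaker response in WT. No gene was called for a difference between the lines in its harman effect (edgeR 0, 365 at unadjusted p below 0.05, DESeq2 0, 1 without WT untreated C, and 33 without the filter on low counts). As with fibrils, moderate differences can be missed. The kinetochore gene SKA1 came nearest (2.83 ± 0.64, adjusted p = 1). ATF4 targets as a list fell less in CG8, by a median of 0.29 (adjusted p = 4.23e-07, adjusted p = 0.255 with an estimated correlation). None of the 33 genes passed alone, also adjusted over the list alone, and examples are SLC7A11 (1.03 ± 0.39) and CHAC1 (1.31 ± 0.56).

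**Figure D2:**
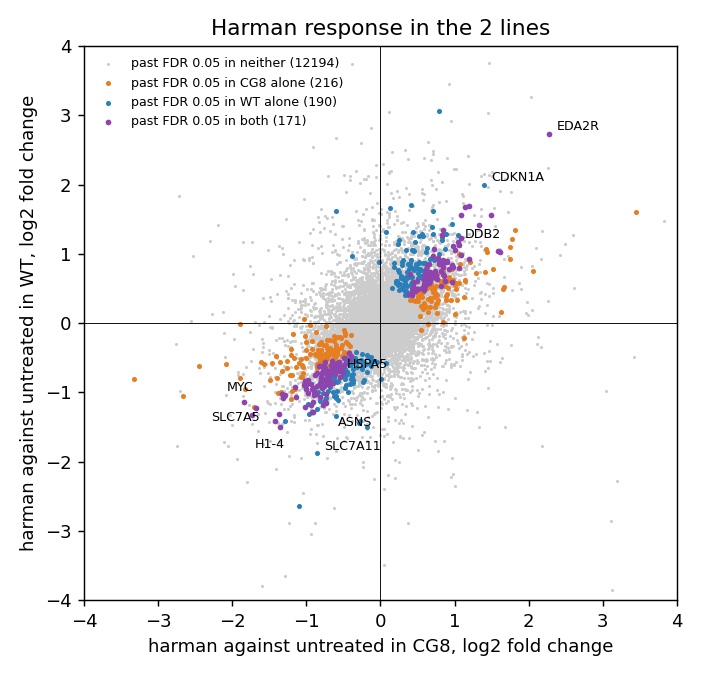
Log2 fold change for harman alone against untreated in CG8 and in WT for each tested gene, coloured by the line in which the gene was called.

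In CG8 cells with fibrils, harman lowered IER2, an immediate early gene (chromosome 19 at 13150415–13154908), by 3.50 ± 0.56 (1.27 ± 0.757 CPM (SD, n = 3) against 15.1 ± 2.61, adjusted p = 0.000469). JUN fell by 2.91 ± 0.51 (13.8 ± 3.0 CPM (SD, n = 3) against 104 ± 13), whereas FOS rose by 2.14 ± 0.40 (adjusted p = 0.00168). Of 15 immediate early genes 2 rose and 4 fell (4 and 4 adjusted over the list alone), and the list was not called (median 0.31, adjusted p = 0.787). IFNGR2, a chain of the interferon-γ receptor, had 0 counts with both agents and was at least 19-fold lower. RPUSD1, a pseudouridine synthase (-3.38 ± 0.51), the sodium-proton exchanger SLC9A3 (-3.19 ± 0.53), the magnesium transporter NIPA2 (-3.09 ± 0.63) and the succinate dehydrogenase assembly factor SDHAF1 (-2.94 ± 0.67) fell. EDA2R rose by 1.88 ± 0.32 (49.5 ± 13.7 CPM (SD, n = 3) against 13.4 ± 2.09). DRP2 of the dystrophin family (2.53 ± 0.67), ACTA2 (1.76 ± 0.29), TBCC, a tubulin-folding factor (1.68 ± 0.30), and CADM2 (1.67 ± 0.35) rose too. DYRK1A rose by 0.73 ± 0.19 (adjusted p = 0.0132), while HSPA5 did not pass (-0.12 ± 0.15, adjusted p = 0.683).

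Fatty acid synthesis was the only list here that held with an estimated correlation. It fell in 4 of 12 genes (6 adjusted over the list alone, median -0.56, adjusted p = 0.000505, adjusted p = 0.0216 with an estimated correlation). These were the ligase ACSL3 (-2.05 ± 0.42), the desaturase FADS1 (-1.63 ± 0.32), FASN (-0.59 ± 0.12) and ACSS2 (-0.94 ± 0.29). FASN lost its fall with length and GC offsets (0.04, adjusted p = 0.945). Endocytosis genes fell in 3 of 24 (4 adjusted over the list alone, median -0.30, adjusted p = 0.0169, adjusted p = 0.209 with an estimated correlation, and adjusted p = 0.183 with offsets). All 3 serve heparan sulfate proteoglycans: HS6ST2 (-0.72 ± 0.18), GPC4 (-1.17 ± 0.37) and SDC3 (-0.79 ± 0.23, but 0.02 with offsets). P53 targets rose in 6 of 21 (7 adjusted over the list alone, median 0.63, adjusted p = 0.000505, adjusted p = 0.231 with an estimated correlation), the p53 antagonist MDM2 by 0.62 ± 0.13 and the BH3 protein PMAIP1 by 0.79 ± 0.19. ATF4 targets fell in 5 of 33 (6 adjusted over the list alone, median -0.06, adjusted p = 0.0449, adjusted p = 0.516 with an estimated correlation), among them SLC7A5 (-1.14 ± 0.18) and the tRNA exporter XPOT (-1.07 ± 0.19). That list call is lost with the replicate block (adjusted p = 0.0536) and with offsets (median 0.02, adjusted p = 0.101), and its median was -0.15 with length-scaled TPM counts.

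Ribosomal protein genes, in contrast, rose in 8 of 57 cases (10 adjusted over the list alone, median 0.45 and 0.28 with offsets, adjusted p = 4.06e-08, adjusted p = 0.516 with an estimated correlation). RPS20 rose by 1.10 ± 0.19 and RPLP1 by 0.96 ± 0.19, and the group made up 3.0 ± 0.173% of gene counts (SD, n = 3). That share was 2.39% with PFF alone, the control here, and 3.35% untreated. The rise thus starts from the low share under fibrils and does not exceed the untreated mean. Respiratory chain genes rose in 6 of 43 and fell in 1 (6 and 1 adjusted over the list alone, median 0.29, adjusted p = 0.00397, adjusted p = 0.516 with an estimated correlation, and adjusted p = 0.141 with offsets), COX4I1 by 0.68 ± 0.16. Mitochondrial mRNAs rose in 3 of 13 (8 adjusted over the list alone, median 0.55, adjusted p = 0.000505, adjusted p = 0.516 with an estimated correlation, and adjusted p = 0.349 with offsets), MT-CYB by 0.41 ± 0.12. G2/M genes rose in 3 of 34 and fell in 1 (7 and 1 adjusted over the list alone, median 0.28, adjusted p = 0.00839, adjusted p = 0.516 with an estimated correlation, and adjusted p = 0.101 with offsets), CKS2 by 0.90 ± 0.21. Glycolysis genes fell in 4 of 28 (4 adjusted over the list alone, median -0.28, adjusted p = 0.00481, adjusted p = 0.516 with an estimated correlation), and hexokinase HK2 fell by 1.32 ± 0.34. Ribosome biogenesis genes fell in 4 of 28 (4 adjusted over the list alone, median -0.24, adjusted p = 0.0082, adjusted p = 0.516 with an estimated correlation), FBL (-1.56 ± 0.25) and MYC (-1.67 ± 0.32) among them. Histones fell in 4 of 26 (5 adjusted over the list alone, median -0.30 and -0.49 with offsets, adjusted p = 0.00863, adjusted p = 0.516 with an estimated correlation), and H2BC18 changed by -1.0 ± 0.17.

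The count for harman on fibrils in CG8 was 1164, 529 up and 635 down. The replicate block gave 1757 (868 up), length-scaled TPM counts 447 (137 up), a test against 1.2-fold 529 (164 up) and a block within each line 2707. Without PFF with harman A, B or C it was 723, 583 or 557, and without PFF A, B or C 746, 668 or 666.

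WT cells with fibrils shared much of this: 76 genes rose and 116 fell in both lines (5.3 and 10.9 expected if independent) and 0 went opposite ways. Across the 1164 CG8 genes, which are not independent replicates, r was 0.82 with slope 0.50, and over all genes 0.49. The 1164 genes were chosen by passing in CG8, so this slope does not show a weaker response in WT either. CDKN1A rose by 1.76 ± 0.43 (180 ± 11.1 CPM (SD, n = 3) against 53.3 ± 12.7). The neuronal microtubule protein MAP2 (2.87 ± 0.64), collagen COL7A1 (2.63 ± 0.72), ACTA2 (2.02 ± 0.33) and EDA2R (1.98 ± 0.42) rose with it. The adaptor SH2D2A (-2.83 ± 0.65), the transcription factor ETS2 (-2.49 ± 0.64), the histone variant H2AX (-2.19 ± 0.53) and REEP6 (-2.14 ± 0.50) fell. ATF4 targets fell in 11 of 33 (14 adjusted over the list alone, median -0.48, adjusted p = 2.05e-11, adjusted p = 0.0984 with an estimated correlation), SLC7A5 by 1.34 ± 0.17 and PSAT1, of serine synthesis, by 1.05 ± 0.20. P53 targets rose in 5 of 21 (7 adjusted over the list alone, median 0.57, adjusted p = 4.15e-07, adjusted p = 0.0847 with an estimated correlation), DDB2 by 1.59 ± 0.24.

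Histones fell in 5 of 26 in these WT cells (10 adjusted over the list alone, median -0.41, adjusted p = 3.91e-06, adjusted p = 0.457 with an estimated correlation), H1-4 by 1.05 ± 0.18. Glycolysis genes fell in 3 of 28 (4 adjusted over the list alone, median -0.25, adjusted p = 0.0175, adjusted p = 0.457 with an estimated correlation, and adjusted p = 0.151 with offsets), the glucose transporter SLC2A1 by 0.87 ± 0.21. Of ribosome biogenesis genes MYC alone fell, by 1.73 ± 0.28 (3 of 28 adjusted over the list alone, median -0.19 and -0.11 with offsets, adjusted p = 0.0191, adjusted p = 0.457 with an estimated correlation). Of fatty acid synthesis genes FASN alone fell, by 0.57 ± 0.12 (3 of 12 adjusted over the list alone, median -0.34, adjusted p = 0.0175, adjusted p = 0.0995 with an estimated correlation), and with offsets neither the list (adjusted p = 0.233) nor the gene (-0.05, adjusted p = 0.935) passed.

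Ribosomal protein genes were higher in WT with both agents than with fibrils alone, where RPS20 rose by 0.71 ± 0.19 (1 of 57, and 0 adjusted over the list alone, median 0.37, adjusted p = 1.27e-08, adjusted p = 0.457 with an estimated correlation). Their share of gene counts was 4.60% with both agents, 3.81% with PFF alone and 4.75% untreated. The proteasome subunit PSMD13 rose by 0.70 ± 0.19 (1 of 32, and 1 adjusted over the list alone, median 0.41, adjusted p = 1.65e-05, adjusted p = 0.457 with an estimated correlation). SDHA of the respiratory chain rose by 0.56 ± 0.14 (1 of 43, and 3 adjusted over the list alone, median 0.29 and 0.19 with offsets, adjusted p = 0.000471, adjusted p = 0.457 with an estimated correlation). G2/M genes rose in 3 of 34 and fell in 1 (6 and 1 adjusted over the list alone, median 0.23, adjusted p = 0.00454, adjusted p = 0.457 with an estimated correlation), the kinase AURKA by 0.50 ± 0.13. The count was 347, 127 up and 220 down. The replicate block gave 854, DESeq2 609, offsets 389, of which 193 were up, and length-scaled TPM counts 110. The compared groups alone gave 47, a test against 1.2-fold 48, no filter on low counts 749 and a block within each line 1795. It rests on single libraries: without PFF B or C it was 103 or 52, without PFF A 570, and without PFF with harman A or B 200 or 65. With the 5 WT libraries that lie apart on PC1 left out it was 71.

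With harman present, fibrils lowered 2 genes in CG8. NET1, an exchange factor for RhoA, fell by 1.54 ± 0.27 (14.1 ± 3.37 CPM (SD, n = 3) against 41 ± 1.48, adjusted p = 0.0413). CLINT1, a clathrin adaptor of the trans-Golgi network, fell by 1.38 ± 0.24 (40 ± 3.35 CPM (SD, n = 3) against 104 ± 14.3, adjusted p = 0.0413). DESeq2 gave 27 calls, the replicate block 47, a block within each line 479, the compared groups alone 234 and no filter on low counts 293. Length-scaled TPM counts, a test against 1.2-fold and leaving out any of the 6 libraries gave 0. Ribosomal protein genes were higher with 0 of 57 past the test (8 rises adjusted over the list alone), with a median of 0.41, or 0.21 with offsets (adjusted p = 5.05e-22, adjusted p = 0.494 with an estimated correlation). In the other 5 lists that moved up no member passed, over all genes or adjusted over the list alone, and none held with offsets.

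These were respiratory chain genes (median 0.25, adjusted p = 2.09e-06, adjusted p = 0.748 with an estimated correlation, and adjusted p = 0.294 with offsets) and proteasome subunits (0.23, adjusted p = 0.000221, adjusted p = 0.789 with an estimated correlation, and adjusted p = 0.117 with offsets). NRF2 targets had a median of 0.24 (adjusted p = 0.00951, adjusted p = 0.0924 with an estimated correlation, and adjusted p = 0.197 with offsets). Histones had 0.25 (adjusted p = 0.00951, adjusted p = 0.789 with an estimated correlation, and adjusted p = 0.764 with offsets). Mitochondrial mRNAs had 0.20 (adjusted p = 0.00951, adjusted p = 0.789 with an estimated correlation), and -0.03 with offsets. The 12 genes that fibrils moved without harman had the opposite sign here. Across them, and genes are not independent replicates, r was -0.78 with slope -0.13 and 0 of 12 kept their sign, while r over all genes was -0.22. The r of -0.78 and its slope lean on the pseudogene GNL3LP1, which has by far the largest fibril effect of the 12. Both also rest on genes chosen by the test without harman, which can enlarge their effects there. PFF alone also serves as the control for harman on fibrils. That shared group gives r = -0.51 across genes in simulated data with no effect, the same as the observed -0.51, while the observed covariance was -0.155 and the simulated one -0.0897.

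Harman and fibrils did not add up in CG8. FAU, which each agent alone left low (31.9 and 46.1 CPM against 73.1 untreated), was at 68.5 ± 10.3 CPM (SD, n = 3) with both, an interaction of 1.76 ± 0.30 (adjusted p = 0.00793, chromosome 11 at 65120628–65122473). CHCHD1 of the mitochondrial ribosome (2.67 ± 0.67, adjusted p = 0.0432), the corepressor CIR1 (1.75 ± 0.39) and LAMTOR5 of the Ragulator complex (1.74 ± 0.34) gave the other large positive terms. IER2 gave -3.85 ± 0.75 (adjusted p = 0.0132). Its mean was 5.06 CPM untreated, 15.1 with fibrils alone, a difference that was not called, and 1.27 with both. The lipid phosphatase PLPP3 (-3.37 ± 0.76), the mitochondrial ubiquitin ligase MARCHF5 (-3.29 ± 0.53, adjusted p = 0.00596) and ETS2 (-3.20 ± 0.73) were the other large negative terms.

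Ribosomal protein genes carried the interaction as a group: 20 of 57 were positive past the test (50 adjusted over the list alone), with RPLP1 (1.65 ± 0.26) and RPL35 (1.67 ± 0.32) in the lead. The median was 0.98 (adjusted p = 3.06e-36, adjusted p = 0.277 with an estimated correlation) and 0.51 with length and GC offsets. Respiratory chain genes were positive in 4 of 43 cases (10 and 1 negative adjusted over the list alone, median 0.58 and 0.22 with offsets, adjusted p = 4.09e-11, adjusted p = 0.35 with an estimated correlation), COX4I1 at 1.24 ± 0.22. Proteasome subunits had 0 of 32 past the test (15 positive and 1 negative adjusted over the list alone, median 0.58 and 0.37 with offsets, adjusted p = 4.74e-09, adjusted p = 0.501 with an estimated correlation). Mitochondrial mRNAs had 0 of 13, also adjusted over the list alone (median 0.42, adjusted p = 0.00931, adjusted p = 0.709 with an estimated correlation), and -0.07 with offsets. NRF2 targets were positive in 2 of 21 cases, the ferritin chain FTL (0.89 ± 0.18) and PRDX1 (1.11 ± 0.28). That held adjusted over the list alone, and the median was 0.24 (adjusted p = 0.027, adjusted p = 0.208 with an estimated correlation, and adjusted p = 0.371 with offsets). With the block and an estimated correlation the ribosomal protein, respiratory chain, proteasome and NRF2 lists each gave adjusted p = 0.0496.

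The interaction count was 164, 72 positive and 92 negative. The replicate block gave 562 (313 positive), DESeq2 333, offsets 110 (29 positive) and length-scaled TPM counts 25 (6 positive). The compared groups alone gave 621, no filter on low counts 583, a block within each line 1148 and a test against 1.2-fold 78. Without untreated A or B it was 47 or 52, without PFF A, B or C 82, 78 or 87, without harman A, B or C 56, 64 or 108, and without both agents A, B or C 67, 81 or 41. The share of counts on ribosomal protein genes had the same order in WT, 4.75 ± 1.11% untreated, 3.81 ± 0.721% with PFF, 3.21 ± 0.554% with harman and 4.60 ± 0.854% with both (SD, n = 3). The share of genes above 4 kb did not add up either. Untreated, with PFF, with harman and with both it was 23.5, 25.6, 27.1 and 25.7% in CG8. In WT it was 20.8, 21.8, 24.2 and 22.8%.

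**Figure D3:**
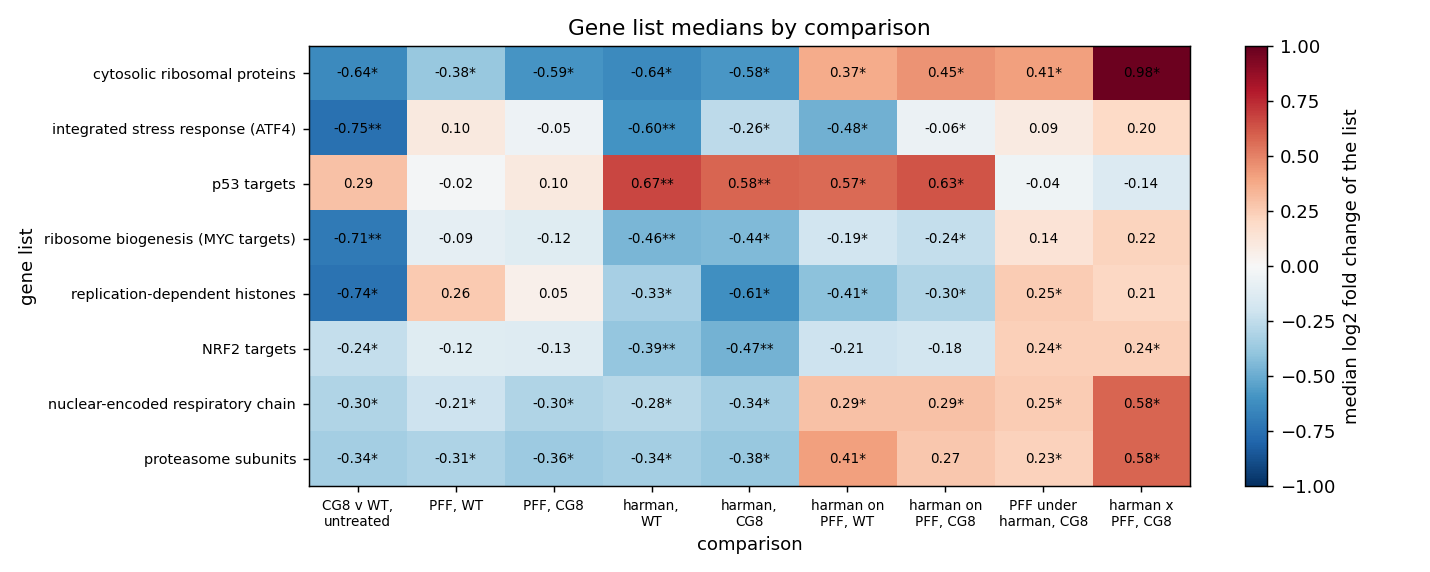
Median log2 fold change of each gene list in each comparison, with marks for lists past an adjusted p of 0.05 in limma camera and for those that also pass with an estimated correlation.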

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

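Every test in this part was written after counts and list results had been seen: the bounds for batches, depth, matched lists, the reporter and the splits were written before their own values were computed, those for offsets on the interaction genes and on ATF4 targets after. The spread used with the reporter bound and the 32 splits that keep batch letters were also chosen after the values were known. What marked each result is a difference between 2 effects that passed a test of that difference. Marked in this way were the ribosomal protein list for fibrils between lines (-0.22), ATF4 targets for harman between lines (0.29), and for harman with fibrils in CG8 the count of 164 genes, CHCHD1 (2.67), FAU (1.76), CIR1 (1.75), LAMTOR5 (1.74), IER2 (-3.85), PLPP3 (-3.37), MARCHF5 (-3.29), ETS2 (-3.20), NRF2 targets (0.24), proteasome subunits (0.58), mitochondrial mRNAs (0.42), respiratory chain genes (0.58) and ribosomal protein genes (0.98).

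The ribosomal protein interaction in CG8 could come from transcript length and GC content, from depth, from 1 batch, or from how the libraries were made. Its median of 0.98 lies at percentile 100 of 10000 lists of other genes matched on length, GC content and CPM (matched median 0.37, central 95% from 0.21 to 0.54), so length and GC content may give part of it, and with offsets 0.51 remains. Thinning all libraries to the smallest leaves 1.00. Random thinning keeps the expected ratios of abundant genes such as these, so this result could hardly differ and does not decide on depth. Batches A, B and C give 1.25, 0.95 and 0.85, so the lowest, 0.85, excludes a single batch. The order in which libraries were prepared or placed on plates is not given and was not tested. The WT median is 0.98 as well.

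The 164 interaction genes may need the reporter, or may follow from fibrils and harman in any cell. Aligned to sign, their median is 1.49 in CG8, 1.23 with length and GC offsets, and 0.89 in WT, where 160 of 164 keep their sign. WT batches A, B and C give 0.67, 0.84 and 0.91 (SD 0.122). A need for the reporter was to show as a WT median below 0.373, and no need as one above 0.745. The WT value lies above the latter by more than the SD. That SD is of batch medians of log2 CPM, not of values from the fit, and batch A does not reach the bound. The bound for no need is therefore not safely passed. Batches A, B and C all lie above 0.373, which argues against an interaction confined to cells with the reporter. The 164 genes and their signs were chosen in the CG8 libraries that give 1.49, which can raise that value and both bounds. The WT value was not chosen so, and the gap from 1.49 to 0.89 does not measure a reporter effect. Whether the reporter adds to the size of the interaction is left open. A direct comparison of the interaction between lines called 0 genes (410 at unadjusted p below 0.05), and WT alone called 1 (350 with the block).

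Lower ATF4 targets in CG8 (median -0.75) could reflect the state of untreated WT cells, 1 batch, or length and GC content. In libraries with PFF, none of which enter the untreated comparison, the median is -0.78, which excludes the untreated WT libraries alone as the source. With harman it is -0.33 and with both agents -0.25, so a state that WT cells without harman share, with or without PFF, stays open. The weakest batch gives -0.69 (A -0.75, C -0.76), and offsets give -0.74. Differences between the lines other than the reporter, such as clonal selection, were not tested.

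Libraries were also regrouped at random. With 3 against 3 there are 10 splits, too few for a share under 0.05, so chance is neither excluded nor not for these. The real split was the only 1 of 10 to reach its count for untreated CG8 against WT (1182, highest other 1), fibrils in CG8 (12, highest other 0), harman in CG8 (387, highest other 0), harman in WT (361, highest other 2), harman on fibrils in CG8 (1164, highest other 1), harman on fibrils in WT (347, highest other 233, a split that joins 3 of the WT libraries that lie apart on PC1) and fibrils under harman in CG8 (2, highest other 1). For the interaction of harman and fibrils 1 of 60 splits reached 164 (highest other 19), and 1 of the 32 splits that keep a library of each batch letter on either side (highest other 0). Both shares are under 0.05, which argues against chance but does not exclude it. The share of 0.0312 is the lowest that 32 splits can give. Most regrouped sets also mix libraries with and without fibrils, which can widen their spread and lower their counts. A real count of 0 is reached by every split whatever the data, so the 10 of 10 for fibrils in WT (highest other 13), 30 of 30 for fibrils between lines (highest other 0) and 30 of 30 for harman between lines (highest other 22) decide nothing.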

How the results depend on the processing

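The settings with length and GC offsets, with a block in each line, without the mitochondrial 16S-like genes, without 5 WT libraries and with treated libraries for CG8 against WT were chosen only after the main counts had been seen; the others were planned. Values are numbers of genes called unless stated, those not printed stayed within 1.5-fold of the main count, and the cause of a move was not tested.

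The replicate block, which pairs libraries by batch letter, gave 1904 for untreated CG8 against WT, 258 for fibrils in CG8, 865 for harman in CG8, 850 for harman in WT, 1757 for harman on fibrils in CG8, 854 for harman on fibrils in WT, 47 for fibrils under harman in CG8 and 562 for the interaction of harman and fibrils in CG8; it changed no other call from none to some. A block in each line gave 669 and 96 for fibrils in CG8 and WT, 1550 and 1577 for harman in CG8 and WT, 2707 and 1795 for harman on fibrils in CG8 and WT, 479 for fibrils under harman and 1148 for the interaction. Offsets for length and GC content gave 182 and 216 for harman in CG8 and WT; offsets with the block gave 69 for fibrils in CG8, 546 for harman in WT, 780 for harman on fibrils in WT, 30 for fibrils under harman and 263 for the interaction.

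DESeq2 gave 153 for fibrils in CG8, 611 and 626 for harman in CG8 and WT, 609 for harman on fibrils in WT, 27 for fibrils under harman and 333 for the interaction. Without a filter on low counts there were 205 and 33 for fibrils in CG8 and WT, 16 and 33 for fibrils and for harman between lines, 749 for harman on fibrils in WT, 293 for fibrils under harman and 583 for the interaction; the stricter filter gave 31 for fibrils in CG8 and 547 for harman in WT. Length-scaled TPM counts gave 528 for CG8 against WT, 0 for fibrils in CG8, 56 and 104 for harman in CG8 and WT, 447 and 110 for harman on fibrils in CG8 and WT, 0 for fibrils under harman and 25 for the interaction. A test against a fold change of 1.2 gave 489, 0, 93, 82, 529, 48, 0 and 78 in the same order. Fits of the compared groups alone gave 680 for CG8 against WT, 78 for fibrils in CG8, 66 for harman in WT, 47 for harman on fibrils in WT, 234 for fibrils under harman and 621 for the interaction. Leaving out 5 WT libraries gave 71 for harman on fibrils in WT. CG8 against WT with PFF gave 2196.

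Leaving out 1 library at a time gave 569–1076 for CG8 against WT, 0–17 for fibrils in CG8, 0–0 for fibrils in WT, 0–1 for fibrils between lines, 143–246 for harman in CG8, 77–486 for harman in WT, 0–1 for harman between lines, 557–746 and 52–570 for harman on fibrils in CG8 and WT, 0–0 for fibrils under harman and 41–126 for the interaction.

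With an estimated correlation the number of called lists went from 15 to 2 for CG8 against WT, 3 to 0 and 4 to 0 for fibrils in CG8 and WT, 1 to 0 for fibrils between lines, 11 to 3 and 12 to 5 for harman in CG8 and WT, 1 to 0 for harman between lines, 11 to 1 and 10 to 0 for harman on fibrils in CG8 and WT, 6 to 0 for fibrils under harman and 5 to 0 for the interaction. Fry gave 0, 0, 0 and 0 for fibrils in CG8, in WT and between lines and for harman between lines, 7 and 5 for harman on fibrils in CG8 and WT, 1 for fibrils under harman and 1 for the interaction. Offsets gave 0 lists for fibrils between lines, 6 for harman on fibrils in CG8, 1 for fibrils under harman and 3 for the interaction, where the replicate block gave 8. Over all genes in place of the called ones, correlations were -0.22 for fibrils without and with harman, 0.23 for fibrils in both lines and 0.40 for harman in both lines.

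Directions turned for DCP2 under fibrils in CG8 (-0.02 with length-scaled TPM counts), for FASN and SDC3 under harman on fibrils in CG8 (0.04 and 0.02 with offsets, 0.04 and 0.03 with offsets and block) and for SLC7A11 in CG8 against WT (0.12 with both agents).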

Other observations

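The comparisons of CG8 with WT under treatment were added only after the untreated result had been seen. They share no library with it. CLCN4 was higher in CG8 by 5.30 ± 0.73, 5.91 ± 0.70 and 3.61 ± 0.52 with PFF, harman and both, OAS3 by 2.40 ± 0.48, 2.79 ± 0.53 and 3.21 ± 0.52, and EDA2R by 1.93 ± 0.42, 1.29 ± 0.31 and 1.83 ± 0.32, all past the test. CA2 (-2.28 ± 0.21, -1.83 ± 0.22, -2.25 ± 0.22), MYC (-1.61 ± 0.28, -2.13 ± 0.32, -1.55 ± 0.33) and the nucleolar GNL3 (-1.71 ± 0.20, -1.43 ± 0.21, -1.71 ± 0.20) were lower each time. MAOA, higher in untreated CG8, did not pass in any of them (1.04, 1.07 and 0.41; adjusted p = 0.104, 0.136 and 0.613).

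With PFF, 51 of 57 ribosomal protein genes fell in CG8 against WT (median -0.84, camera adjusted p = 1.9e-25; adjusted p = 0.174 with an estimated correlation), 19 of 33 ATF4 targets fell and 1 rose (median -0.78; adjusted p = 0.0636 with an estimated correlation) and 5 of 24 endocytosis genes rose (median 0.25, adjusted p = 0.011; adjusted p = 0.0636 with an estimated correlation). Under harman alone 12 ATF4 targets fell, 1 rose and the median was -0.33 (adjusted p = 0.000149; adjusted p = 0.272 with an estimated correlation). With both agents 11 of 33 fell and the median was -0.25 (adjusted p = 5.42e-06; adjusted p = 0.178 with an estimated correlation). Of 28 ribosome biogenesis genes 17 fell with PFF (1 rose), with harman and with both. Their medians were -0.74, -0.72 and -0.81 (adjusted p = 6.19e-12, 5.7e-13 and 3.65e-15, and 0.0636, 0.121 and 0.0418 with an estimated correlation). With both agents 6 of 30 S phase genes fell (median -0.29, adjusted p = 0.000111; adjusted p = 0.0418 with an estimated correlation). The counts were 2196 with PFF, 1321 with harman and 1536 with both. Lists of tissue marker genes with fewer than 5 tested members were not tested between the lines.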
